A study of Mus musculus with 44 samples.

How the data were processed

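The series holds 44 mouse libraries in 19 groups. RNA was measured in 20 libraries from the paraventricular thalamic nucleus (PVT), in 5 groups of 4. Chromatin immunoprecipitation for H3K27ac, a histone mark of active promoters and enhancers, covered 16 libraries from 4 brain regions with 2 wild-type (WT) and 2 Polg(D181A) libraries per region. ATAC-seq, which reads open chromatin, covered 4 PVT libraries. The 4 input libraries mixed both genotypes and were not used here. Nuclei for ATAC-seq and H3K27ac were sorted on NeuN, a neuronal nuclear protein, per the labels' protocols. RNA libraries were made with a low-input total RNA kit, per the labels. Groups were taken from the labels, and no value was used to place a sample in a group. The labels do not say whether the replicates of a group came from separate animals, so p-values measure the spread between these samples, which can be technical.

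Every table used here holds raw read counts as deposited, per gene for RNA and per peak for chromatin, as whole numbers whose column totals differ. The submitters' processing notes name STAR, HOMER, Subread, featureCounts and DESeq2 and the build mm10, with no role, order or version. Which features the RNA reads were counted over, exons or whole gene spans, and whether strand was used are not given in the sources used here. Duplicate removal and the peak threshold are likewise not given in the sources used here. Each chromatin table has 1 merged peak set for its 4 libraries and no other value per peak. Per the file headers, RNA columns carry their group and no replicate number, so RNA columns were never paired with samples of another group.

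Gene identifiers were matched to symbols for 53620 of the 53715 genes of the RNA table. Total counts ranged from 26719334 to 115285349 per RNA library and from 2932270 to 8040451 per ATAC library. H3K27ac totals ranged from 52759552 to 146450422 in PVT and from 52566179 to 197650530 in cortex (COR). They ranged from 12048787 to 101443484 in caudate putamen (CP) and from 6415127 to 80516545 in nucleus accumbens (NAC). Reads carried no molecular identifiers in these tables, so counts are not independent molecules. CPM were computed on library sizes scaled by trimmed mean of M values (TMM), and a mean is given with its SD over the n libraries of the group.

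The main test was the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, edgeR's own filter on low counts, robust dispersion and Benjamini-Hochberg adjustment, 2-sided, at an adjusted p under 0.05. All 20 RNA libraries entered 1 model with a mean per group, which left 15 residual degrees of freedom and 28446 tested genes. The model takes libraries as independent, although the labels do not say whether COX-positive and COX-negative libraries of a state came from the same animals. Each chromatin table was fitted alone. Gene lists, 48 in number, were fixed before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. The RNA table allowed a test of 46 lists. The 37 mitochondrial genes of the table held 0 counts in every library, so the mitochondrially encoded lists were among the 2 that were not testable.

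Peaks were placed with a gene table of the assembly GRCm38.p6, which is mm10, and GenomicRanges 1.54.1. The table has no strand, so the planned promoter window was replaced by a peak within 1000 bp of either end of a protein-coding gene, called a gene-end peak below. The nearest gene of a peak outside genes is given as a landmark. For tests across regions, counts of gene-end peaks were summed per gene over the 5029 genes with such peaks in all 4 H3K27ac tables, with region and genotype in 1 model. Peaks were drawn separately for each region, so such sums also move with the length called as peak.

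Named genes followed a fixed rule. Polg and the mitochondrial mRNAs were always named. For each RNA contrast, 10 genes of smallest p per direction were taken among those past the threshold with a mean of at least 5 CPM in a group, leaving out predicted loci, with up to 4 passing members of each list. Where fewer than 5 passed, the 5 genes of smallest p were taken and are given as values that did not pass. For each chromatin table, 5 peaks of smallest p per direction past the threshold, or else the 5 of smallest p, were taken with all peaks in Polg. For the test of region by genotype, 10 genes of smallest p were taken. Camk2a was singled out after its values had been seen. Values of some single marker genes are not reported here.

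Alternatives fixed before the data were examined were DESeq2 size factors, total counts only, no filter, a stricter filter (10 counts in at least 8 RNA libraries), only the groups of a contrast, limma's voom with quality weights, the number of detected genes as a covariate, DESeq2 1.42.0, a replicate block for chromatin, a window of 500 bp, and leaving out each library. Where a library left out leaves 1 library in an arm, the lone library is taken to vary like the other groups. Chosen after the data had been seen were the RNA fit without 14 satellite-like loci, the comparison of each region with the other regions, its version per kb of peak, the tests of the Polg and Camk2a loci with a pseudocount of 1 CPM, the tests of marker lists for gene-end peaks with both of their alternatives, camera with gene-end peaks alone as background, and the left-out libraries in the tests of genotype by region and averaged over regions and in the correlations of changes between contrasts. The count of DESeq2 calls over other splits was run in 3 forms to fit the run time. Its genes and number of splits were set after the earlier forms had been seen, and all 3 forms gave most splits as many calls as the real grouping.

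The tests were run on simulated counts with the real genes, library totals and fitted spread, and with 100 features changed 4-fold and 100 changed 16-fold. At the fitted spread of the RNA table the genotype contrast recovered 0 of 100 at either size, so changes of that size were not detectable in the simulation. The contrast of behavioural states averaged over COX classes recovered 0 and 4 of 100. With a coefficient of variation of 0.2 in place of the measured one, added afterwards as a check of the code, 98 and 100 of 100 were recovered with 10 false calls. ATAC recovered 18 and 55 of 100, H3K27ac PVT 1 and 16, COR 2 and 14 with 55 false calls, and CP and NAC 0 of 100 at either size. Gene-end tests recovered 15 and 59 of 100 averaged over regions with 7 false calls, 0 at either size for region by genotype, and 7 and 39 for PVT against other regions. Unchanged features passed an unadjusted p under 0.05 in 3.80% of cases in the simulated RNA genotype contrast. The real contrast had 4357 such genes of 28446 (15.3%), and other splits of its libraries had 4127 to 5287. The simulated counts thus did not behave like the real ones, and the recovery values describe the simulation only.

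Exact permutation tests enumerated every assignment of genotype labels within each table. Over several chromatin tables they take the tables as independent, which the labels do not establish, since tables may share animals. Other splits of the libraries were counted in full where there were at most 100 and otherwise drawn 100 times with a fixed seed. Gene counts from overlapping genes, near-identical copies such as ribosomal protein pseudogenes and clustered olfactory receptor genes are uncertain, since how shared reads were counted is not given in the sources used here.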

Results

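The samples came from wild-type (WT) mice and from mice with Polg(D181A), a mutant form of the polymerase that copies mitochondrial DNA. The mutant line is studied as a model of bipolar disorder. RNA was counted in 20 libraries of the paraventricular thalamic nucleus (PVT), a midline thalamic nucleus. They were sorted in the labels by behavioural state, euthymic or depressive, and by staining for cytochrome c oxidase (COX), which is complex IV of the respiratory chain. There were 4 WT libraries, all euthymic and COX-positive, and 4 mutant libraries for each combination of state and COX class. H3K27ac was counted over peaks in PVT, cortex (COR), caudate putamen (CP) and nucleus accumbens (NAC), and open chromatin was counted by ATAC-seq in PVT, with 2 WT and 2 mutant libraries per table.

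RNA libraries of a group resembled each other no more than libraries of different groups did. The rank correlation of counts over genes had a median of 0.634 over the 30 pairs within groups (range 0.587 to 0.729) and 0.641 over the 160 pairs between groups (range 0.580 to 0.740). Between 27148 and 42978 genes had a count in a library (mean 33519 ± 3140, SD, n = 20). A set of 14 satellite-like loci took from 0.131% to 83.3% of a library's counts. Counts followed the genomic span of the gene in every library, with a rank correlation across genes of 0.793 to 0.878. The 37 genes of the mitochondrial genome, among them those for core subunits of the respiratory chain, were listed at 0 counts in all 20 libraries, so they were not compared. The common biological coefficient of variation was 1.37.

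Polg (ENSMUSG00000039176) was first compared in every library, because the mutant line carries a mutant form of it. As background that is not stated in the labels, that form is carried by a transgene. WT libraries held 0.946 to 3.69 CPM of Polg and mutant libraries 0.559 to 199.9 CPM, and 11 of 16 mutant libraries lay above the highest WT library. Mean log2(CPM + 1) was 1.80 ± 0.57 in WT (SD, n = 4) and 4.26 ± 2.61 in the mutants (SD, n = 16), a difference of 2.46. An exact permutation test over 4845 assignments gave a 2-sided p of 0.0871, so the difference did not pass. A rise in mutants of that size or larger was found for 13 of 28446 genes, Polg included, and falls of that size were not counted. WT libraries were all euthymic and COX-positive, while the mutants covered both states and both COX classes. These values therefore mix genotype with state and COX class. In euthymic COX-positive mutants alone, 1 of 4 libraries lay above the WT median, with a median of 1.61 against 3.02 CPM. Group means were 50.9 ± 99.3 CPM in euthymic COX-positive mutants, 59.9 ± 56.8 in euthymic COX-negative, 47.0 ± 45.6 in depressive COX-positive and 73.5 ± 93.4 in depressive COX-negative ones (SD, n = 4 each).

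**Figure D1:**
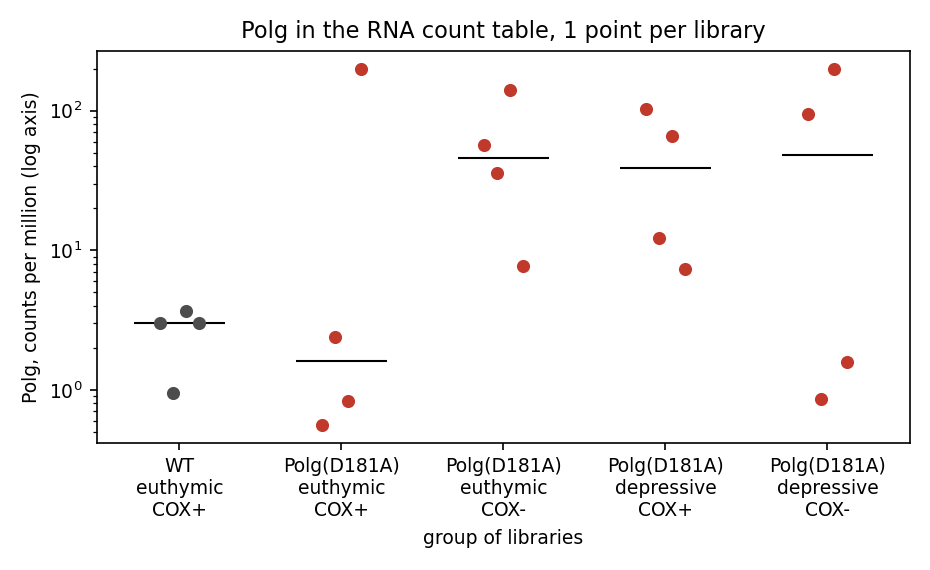
Polg CPM (log axis) in each of the 20 RNA libraries, by group; each point is a library and each bar is the group median. The 4 WT libraries lie between 0.946 and 3.69 CPM and the 16 mutant libraries between 0.559 and 199.9 CPM.

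The comparison of mutant with WT libraries in euthymic COX-positive samples asked what the mutation did to RNA where COX staining was kept. The genes of smallest p were Myl6, a myosin light chain, Ormdl1, a regulator of sphingolipid synthesis, Neurod4, a neurogenic transcription factor, the olfactory receptor pseudogene Olfr721-ps1 and the defensin gene Defb50. All 5 were below the WT median in 4 of 4 mutant libraries. Myl6 had 0.0305 ± 0.0191 CPM in mutants and 540.4 ± 1075 in WT (log2 change −14.00), and Ormdl1 had 0.166 ± 0.118 and 391.1 ± 754.2 CPM (log2 change −11.19). Neurod4 had 0.343 ± 0.263 CPM in mutants and 477.5 ± 952.5 in WT. These WT means rested on few libraries, as their SDs show (n = 4 each).

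None of these genes passed. The edgeR test called 0 of 28446 genes, with a smallest adjusted p of 0.179, while 4357 genes had an unadjusted p under 0.05. Other splits of these 8 libraries into groups of 4 gave 4127 to 5287 such genes. DESeq2 called 1125 genes, voom 0 and edgeR without a filter on low counts 2. Polg had a log2 change of 4.25 (SE 1.79, adjusted p = 0.273, edgeR), with 1 of 4 mutant libraries above the WT median. Without the euthymic COX-positive mutant library with 199.9 CPM of Polg the log2 change was −1.06.

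Nuclear genes of complex IV, the enzyme whose staining defines the COX classes, had the smallest list p between mutant and WT. Their 10 measured members had a mean log2 CPM of −0.25 ± 0.98 in WT and −1.90 ± 0.25 in euthymic COX-positive mutants (SD, n = 4). The other mutant groups stood at −1.55 ± 0.37 (euthymic COX-negative), −0.87 ± 0.66 (depressive COX-positive) and −1.49 ± 1.39 (depressive COX-negative). The median log2 change in the comparison was −2.12, which did not pass with camera (adjusted p = 0.123), and 0 of the 46 lists passed with camera, with an estimated correlation (adjusted p = 0.999 for complex IV) or with fry. Without adjustment, 2 lists had a camera p under 0.05. No gene of any list was called over all genes, and 24 list members passed when adjusted over the list alone, against 15 to 42 in other splits of these libraries.

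Markers of glia were measured beside these lists. Astrocyte markers had a mean log2 CPM of 1.41 ± 0.68 in WT libraries and group means of 0.53 to 0.998 in the mutants. Oligodendrocyte markers had 0.99 ± 0.44 in WT and −0.01 to 0.32 in the mutants. PVT and midline thalamus markers had 2.31 ± 0.48 in WT and 1.98 to 2.33 in the mutants. None of these marker lists passed in any RNA comparison. Glycolysis and lactate genes had 1.56 ± 0.36 in WT and 0.89 to 1.09 in the mutants. For p53 targets and apoptosis genes these values were 0.89 ± 0.41 and 0.19 to 0.39. Higher WT values were thus not particular to glia, although some lists, such as the PVT list, were not highest in WT.

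COX-negative and COX-positive mutant libraries were compared to find RNA that goes with loss of COX activity. In euthymic mice, Amer3, which codes for an APC-binding protein, had 173.2 ± 229.3 CPM in COX-negative and 0.455 ± 0.482 in COX-positive libraries. Hfe, an iron regulator, had 154.3 ± 263.1 against 0.0653 ± 0.0353 CPM. The transcription factor gene Hey1 had 66.5 ± 132.5 against 0.0430 ± 0.0246 CPM. Rps14, a ribosomal protein gene, was at 0 in all 4 COX-negative libraries and at 48.4 ± 93.6 CPM in COX-positive ones, and Psmb5, a proteasome subunit gene, had 0.0288 ± 0.0416 against 25.6 ± 50.5 CPM (SD, n = 4). None passed (adjusted p = 0.123, edgeR).

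In depressive mice the genes of smallest p in that comparison were Olfr23, Prg4, Olfr1235-ps1, Ivl and Slco1a6. Prg4, which codes for lubricin, had 112.9 ± 144.7 CPM in COX-negative and 0.121 ± 0.0478 in COX-positive libraries. Slco1a6, an organic anion transporter gene, had 5.14 ± 2.37 against 354.1 ± 513.9 CPM (log2 change −6.11). Olfr23, an olfactory receptor gene, had 59.9 ± 76.8 against 0.0217 ± 0.0193 CPM (SD, n = 4). None passed (adjusted p = 0.132, edgeR).

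Averaged over both states, S100a4, a calcium-binding protein gene, lay above the COX-positive median in 8 of 8 COX-negative libraries. Its mean was 20.1 ± 37.1 against 0.0220 ± 0.0372 CPM. Mcfd2, a cargo receptor gene of the secretory pathway, had 0.0987 ± 0.0839 against 41.4 ± 74.8 CPM, and Card19 had 0.0934 ± 0.0564 against 19.3 ± 45.6 CPM, each below the COX-positive median in 8 of 8 libraries. Hfe had 77.5 ± 190.8 against 0.0523 ± 0.0357 CPM and was above that median in 7 of 8 libraries, as was the septin gene Sept5 (SD, n = 8). None passed (adjusted p = 0.0538, edgeR). Polg had log2 changes of 0.23 in euthymic mice, 0.65 in depressive mice and 0.44 averaged.

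The edgeR test called 0 genes for COX class in euthymic mice, in depressive mice and averaged over states. Unadjusted p under 0.05 was found for 6040, 5667 and 6475 genes, against 5804 to 6325, 5550 to 6921 and 6097 to 7254 in other splits of the libraries. DESeq2 called 2103, 2019 and 2192, and voom called 0 in each. Without a filter on low counts edgeR called 458, 586 and 1628 genes, and averaged over states it called 377 with DESeq2 size factors, 283 with a stricter filter and 317 without satellite-like loci. Genes linked to bipolar disorder by association studies had a median log2 change of 0.71 over 37 measured members in euthymic mice (camera adjusted p = 0.257), the smallest of any list. Adjusted over the list alone, 65, 35 and 77 list members passed, against 39 to 77, 22 to 64 and 60 to 119 in other splits.

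Depressive and euthymic mutant libraries were compared to find RNA that goes with the behavioural state. Averaged over COX classes, 354 of 28446 genes passed with edgeR, 172 higher and 182 lower in depressive libraries. Of 100 splits of the mutant libraries, the real one included, 49 gave as many genes and the highest gave 2121, and no gene passed without any 1 of the 16 libraries. Among genes that rose were Glce, an enzyme of heparan sulfate synthesis (log2 change 4.75, SE 1.08), with 230.0 ± 433.5 CPM in depressive and 7.49 ± 9.43 in euthymic libraries and 7 of 8 depressive libraries above the euthymic median. Frmd8, with 92.1 ± 187.5 against 1.42 ± 2.39 CPM, and Inca1, a cyclin-dependent kinase inhibitor gene with 72.2 ± 122.7 against 0.571 ± 0.445 CPM, lay above that median in 6 of 8. The olfactory receptor gene Olfr397 rose (log2 change 8.97), as did Btbd35f18, Vmn1r201, Ly6f and Ecel1 (log2 change 11.31, 7.36, 7.99 and 7.11) and Spint4, which was at 0 in all euthymic COX-negative libraries.

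The leading genes that fell in the depressive libraries were each below the euthymic median in 8 of 8. Eppk1, which codes for epiplakin, had 0.445 ± 0.326 CPM in depressive and 216.4 ± 360.9 in euthymic libraries (log2 change −8.72, SE 1.62). Prrc2b, an RNA-binding protein gene, had 4.04 ± 2.84 against 173.2 ± 232.9 CPM (log2 change −5.08, SE 1.04), and Amer3 had 0.116 ± 0.0445 against 86.8 ± 176.2 CPM (log2 change −6.24, SE 1.25). Gif, which codes for gastric intrinsic factor, had 0.402 ± 0.248 against 95.5 ± 167.8 CPM, and Mrm2, a mitochondrial rRNA methyltransferase gene, had 0.133 ± 0.137 against 34.0 ± 56.0 CPM. Gprasp2, Olfr101, Klhl36 and Pcdh18 fell as well, with log2 changes of −10.18, −7.91, −7.41 and −6.99. Means are over n = 8 libraries per state, with SD. If COX-positive and COX-negative libraries share animals, which the labels do not say, these 8 are not independent replicates.

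Members of the fixed lists among the 354 genes went both ways. In mitochondrial lists, Pink1, a kinase that starts mitophagy, rose (log2 change 5.17; 40.6 ± 101.9 against 0.212 ± 0.137 CPM) and the complex I subunit Ndufa11 fell (log2 change −5.64). Of ribosomal protein genes, Rps26 rose (log2 change 8.71) while Rps25 and Rps27a fell (log2 change −9.70 and −6.74). Rps26 had medians of 0.145 CPM in depressive and 0.0225 in euthymic libraries, and 5 of 8 depressive libraries lay above the euthymic median. The chaperone gene Dnaja1, the ER ubiquitin ligase gene Syvn1 and Gclc, an enzyme of glutathione synthesis, rose by log2 changes of 5.65, 6.25 and 5.99. Nr4a2, an immediate early gene, fell (log2 change −5.77). The channel gene Hcn3 and the ghrelin receptor gene Ghsr also fell, by log2 changes of −5.97 and −5.69, in 8 of 8 libraries, and the neuropeptide gene Tac2 rose (log2 change 6.48), although 4 of 8 depressive libraries lay above the euthymic median.

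Glial markers went both ways too. The astrocyte genes Mlc1 and S100b fell and rose (log2 change −6.27 and 5.24), and Olig2, of the oligodendrocyte lineage, rose (log2 change 6.68). No list passed (smallest camera adjusted p = 0.712, mitochondrial dynamics and mitophagy, median log2 change 0.38 over 26 members), and 91 list members passed when adjusted over the list alone, against 60 to 137 in other splits. Adjusted p was 0.0485 for most of the named genes and at most 0.0498. The count of 354 fell to 0 without any 1 of the 16 mutant libraries, with voom, with the number of detected genes as a covariate and with only the 4 mutant groups in the model. With DESeq2 size factors edgeR called 780, with 1887 without a filter on low counts, 206 with a stricter filter and 670 without satellite-like loci. DESeq2 called 2110 genes, 156 of them among the 354.

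Within COX classes no gene passed for behavioural state. In COX-negative libraries, Amer3 had 0.109 ± 0.0540 CPM in depressive and 173.2 ± 229.3 in euthymic samples, and Fbxw4, an F-box protein gene, had 3.48 ± 2.61 against 341.0 ± 426.1 CPM (log2 change −6.61). Pcdh18, a protocadherin gene, had 0.0954 ± 0.0959 against 237.0 ± 469.4 CPM and Fam217b had 0.0995 ± 0.110 against 150.2 ± 243.6 CPM, and the fifth gene was Uts2, which codes for urotensin 2. In COX-positive libraries, Krt71 had 0.0195 ± 0.0238 against 27.6 ± 40.6 CPM and Gmfg had 415.9 ± 830.9 against 0.518 ± 0.522 CPM (SD, n = 4 each), beside Calhm4, Gsdmcl-ps and Thap11. The edgeR test called 0 genes in COX-positive and 0 in COX-negative libraries (smallest adjusted p = 0.136 and 0.0862). Unadjusted p under 0.05 was found for 4980 and 6432 genes, against 4927 to 6293 and 6308 to 7115 in other splits. DESeq2 called 1733 and 2537 and voom 1 and 1, and edgeR without a filter called 0 and 1170. Polg had log2 changes of −0.12 and 0.30. Complex IV genes had a median log2 change of 2.04 in COX-positive libraries and cholesterol synthesis genes −1.03 (camera adjusted p = 0.362 for both lists), and adjusted over the list alone 33 and 92 list members passed, against 15 to 39 and 83 to 126 in other splits.

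The interaction asked whether the COX difference depended on behavioural state. Olfr23, Npy6r, a neuropeptide Y receptor gene, and Clec1b, a platelet receptor gene, had interaction estimates of 14.92, 18.02 and 15.11 on the log2 scale. The ribosomal protein gene Rpl26 and Armc1, a gene for a protein of the mitochondrial outer membrane, had −15.40 and −15.31. None passed: edgeR called 0 genes (smallest adjusted p = 0.0534), 6344 had an unadjusted p under 0.05 (6111 to 7178 in other splits), DESeq2 called 1976 and voom 0. With DESeq2 size factors edgeR called 378, with 1582 without a filter on low counts, 188 with a stricter filter and 280 without satellite-like loci. Genes linked to bipolar disorder had a median of −1.40 (camera adjusted p = 0.168), and 87 list members passed when adjusted over the list alone, against 59 to 129 in other splits.

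COX differences were correlated across genes between euthymic and depressive mice, and state differences between COX-positive and COX-negative libraries. Across 28446 genes, the COX differences of euthymic and depressive mice correlated at r = 0.00895 (Spearman 0.0105) and had the same sign in 50.5% of genes. The state differences of COX-positive and COX-negative libraries correlated at r = 0.00948 (Spearman 0.00474), with the same sign in 50.01%. Genes are not independent replicates, so no p is given. The differences set against each other shared no library. No gene was called with edgeR in these 4 contrasts, where 4980 to 6432 genes had an unadjusted p under 0.05, so a correlation near 0 does not show that differences fail to recur.

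The number of marker genes with an H3K27ac peak at a gene end was counted in each brain region, and the difference between regions was not tested. Of 18 striatal projection neuron markers, all 18 had a gene-end peak in CP and 15 in NAC, against 11 in PVT and 10 in COR. Of 16 inhibitory neuron markers, 12 had a peak in CP, 10 in NAC and 7 in COR, and in PVT only Npy and Pvalb did. Of 17 hippocampal and cortical neuron markers 15 had a peak in COR, and of 25 PVT and midline thalamus markers 20 had a peak in PVT, with 12 to 15 in the other regions. Microglia markers had a peak in 3 of 21 genes in PVT, and hemoglobin and blood markers in 2 of 13 in PVT and in COR and in 0 of 13 in CP and NAC.

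**Figure D2:**
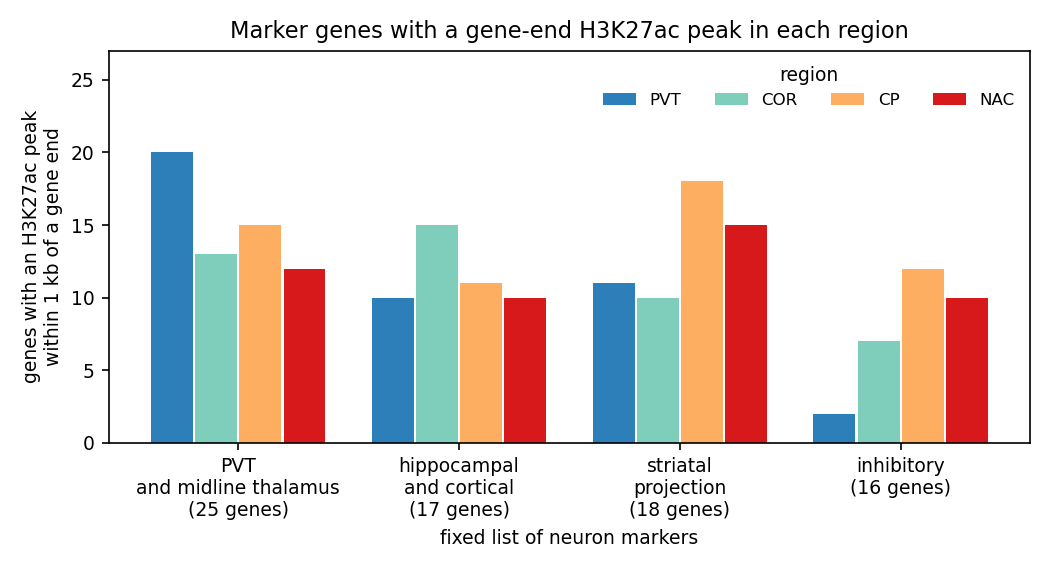
Number of genes in 4 fixed lists of neuron markers with an H3K27ac peak within 1 kb of a gene end (vertical axis, genes) in each region; bars are counts and list sizes stand under the names. Striatal markers reach 18 of 18 in CP, cortical markers 15 of 17 in COR, PVT markers 20 of 25 in PVT, and inhibitory markers 2 of 16 in PVT.

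The transcription factor genes of the thalamus Gbx2, Tcf7l2 and Zic1 had gene-end peaks of 535.1 ± 99.3, 397.2 ± 53.7 and 292.9 ± 105.2 CPM in PVT and none in the other regions (SD, n = 4 per region, both genotypes together). Calb2 had 201.8 ± 65.5 CPM in PVT alone. Other genes of the PVT list went the other way: Slc17a6 had no such peak in PVT and 87.2 ± 16.4 CPM in COR, Calb1 had none in PVT and 137.5 ± 99.4 in NAC, Drd3 had 10.5 ± 13.1 in PVT and 381.7 ± 317.2 in NAC, and Drd2 had 18.8 ± 9.76 in PVT and 221.9 ± 172.3 in CP. Emx1, of cortical projection neurons, had 191.7 ± 84.4 CPM in COR alone. Gad1, the enzyme that makes GABA, had 879.5 ± 599.6 CPM in CP and 388.2 ± 49.2 in NAC and none in PVT or COR, and Ppp1r1b, which codes for DARPP-32, had 585.7 ± 351.4 in CP and 631.4 ± 167.7 in NAC against 89.1 ± 23.5 in PVT.

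These lists were set against all other protein-coding genes with Fisher's exact test, 48 tests in all, chosen after the counts had been seen. Adjusted p was 5.18e-06 for striatal markers in CP (100% of genes against 40.99%) and 0.0409 in NAC (83.3% against 50.4%), 0.0223 for cortical markers in COR and 0.0577 for PVT markers in PVT, which did not pass. Inhibitory markers were less often marked in PVT than other genes (12.5% against 55.1%, adjusted p = 0.00747) and more often in CP (adjusted p = 0.0424). Adjusted p was 0.00328 for microglia markers in PVT, 0.0409 for endothelial markers in NAC (7 of 28 genes), and 0.0308, 0.0433, 0.0117 and 0.00264 for blood markers in PVT, COR, CP and NAC. Gad1 is in the inhibitory and striatal lists, Drd2 in the PVT and striatal, Prox1 in the PVT and cortical and Bcl11b in the striatal and cortical lists. Either a 500 bp window or a count minimum ended the call for inhibitory markers in CP (0.105 and 0.137) and cortical markers in COR (0.586 and 0.0660), while 1 of them ended it for endothelial markers in NAC (0.0552) and blood markers in COR (0.105) and CP (0.147), and PVT markers in PVT passed with the count minimum (0.0487) but not with the 500 bp window (16 of 25 genes, 0.526).

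Over its whole span (mm10, chromosome 7, 79446231 to 79467911), Polg held more peak reads in both mutant libraries than in both WT libraries in 4 of 5 chromatin tables, with a mean difference of 1.76 on the log2(CPM + 1) scale (SD 1.60 over tables, exact permutation of genotype within tables, 2-sided p = 0.00180). Without the NAC table, where the WT libraries had 2.78 and 0 CPM, the mean was 1.11 (exact p = 0.0108). Both permutation tests take the tables as independent. The labels do not say whether libraries of different tables came from the same animals, in which case both p would be too small. The median log2 change of all peaks was 0.66 in CP and 1.09 in NAC, where 80.8% and 69.6% of peaks were at 0 in the WT 2 library, and −0.0024, −0.0029 and 0.10 in ATAC-seq, PVT and COR. In COR, with 38.1 ± 14.5 CPM in mutants and 34.3 ± 26.4 in WT, the libraries overlapped. A part of the span, without its upper 2000 bp, was chosen after the values had been seen. There both mutant libraries exceeded both WT libraries in 5 of 5 tables. Summed peaks there had 17.5 ± 8.12 CPM in mutants and 1.81 ± 1.51 in WT by ATAC-seq and 26.9 ± 0.122 against 6.50 ± 2.37 by H3K27ac in PVT. The other regions had 37.1 ± 15.96 against 13.5 ± 9.32 in COR, 107.1 ± 17.3 against 37.4 ± 30.4 in CP and 39.6 ± 4.28 against 1.39 ± 1.97 in NAC (SD, n = 2 each). A peak in the CP sum, from 79449802 to 79450125 with 23.4 ± 19.6 CPM in mutants and 0 in WT, also lies in the neighbouring gene Fanci. The mean difference over tables was 2.46 (SD 1.17), or 1.77 with a pseudocount of 5 CPM in place of 1, with no p given for a part chosen in this way. At the upper end of the gene the mean difference was −0.92 (SD 2.15 over 3 tables). Mutants had 25.2 ± 3.12 CPM there against 25.1 ± 0.470 by ATAC-seq, 4.97 ± 3.08 against 2.62 ± 0.209 by H3K27ac in PVT, where both mutant libraries exceeded both WT libraries, and 1.02 ± 1.44 against 20.8 ± 17.1 in COR.

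Camk2a, which codes for the alpha subunit of a calcium-dependent kinase of forebrain neurons (mm10, chromosome 18, 60925307 to 60988152), was chosen after its values had been seen, and so was the part compared. The peak at its lower end had 210.1 ± 4.84 CPM in mutants and 78.6 ± 23.2 in WT by ATAC-seq in PVT, 577.3 ± 65.7 against 253.8 ± 120.0 in COR, 237.4 ± 7.91 against 72.1 ± 94.0 in CP and 742.9 ± 65.6 against 199.8 ± 58.2 in NAC (SD, n = 2 each). Both mutant libraries exceeded both WT libraries in 4 of 4 tables, with a mean log2 difference of 1.90 (SD 0.77, 3.72-fold), and no p is given for a locus chosen in this way. Over the rest of Camk2a the difference was −0.05 (SD 0.30 over 5 tables). H3K27ac in PVT had no peak at the lower end of Camk2a. The COR and NAC peaks reach from Camk2a into the neighbouring gene Arsi.

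**Figure D3:**
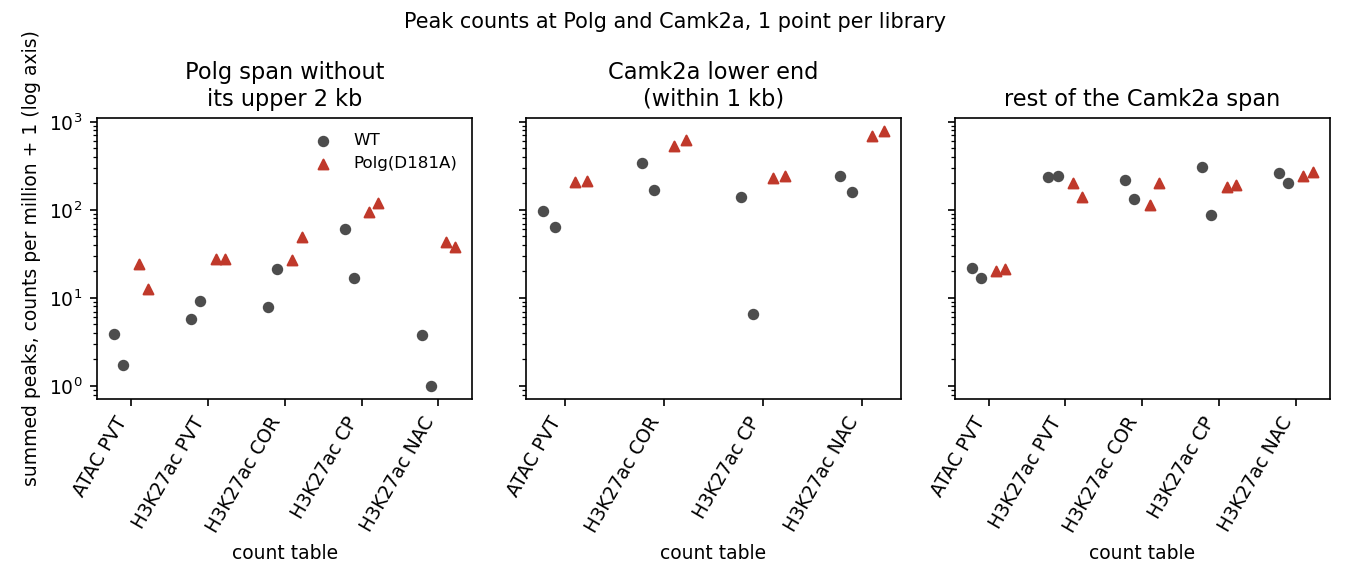
Summed peak CPM plus 1 (log axis) in each chromatin library over the Polg span without its upper 2 kb, the lower end of Camk2a and the rest of Camk2a, by table; circles are WT and triangles mutant libraries. Mutant libraries lie above WT libraries in all 5 tables at Polg and all 4 at the lower end of Camk2a, and in 0 of 5 over the rest of Camk2a.

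Each chromatin table was also searched peak by peak for a difference between genotypes. In ATAC-seq of PVT neurons 1 of 87600 peaks passed, on chromosome 18 from 39868433 to 39868761, outside genes and 92350 bp from Pabpc2, and it was lower in mutants (7.39 ± 2.42 against 66.8 ± 17.9 CPM, log2 change −3.14, SE 0.37, adjusted p = 0.0235, edgeR). A peak in Polg on chromosome 7 from 79453797 to 79454119 had 17.5 ± 8.12 against 1.81 ± 1.51 CPM, and a peak in Chd9, a chromatin remodeler gene, on chromosome 8 from 91006650 to 91006972 had 10.98 ± 5.66 against 0.248 ± 0.174 CPM. Neither passed (adjusted p = 0.704), nor did peaks in Irf2 and near Tmprss4. The Polg peak from 79466096 to 79466520 had 25.2 ± 3.12 against 25.1 ± 0.470 CPM (SD, n = 2 each). DESeq2 called 3 peaks, and the edgeR call was lost without the WT 1 library, while 4 peaks passed without Polg 1.

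H3K27ac peaks in PVT and COR showed differences that did not pass. In PVT, a peak 8587 bp from Klf17 on chromosome 4 from 117774254 to 117777415 had 3.92 ± 0.270 CPM in mutants and 24.4 ± 0.222 in WT (log2 change −2.64), and a peak near Ebpl on chromosome 14 from 61362101 to 61362852 had 9.24 ± 1.15 CPM in mutants and 0 in both WT libraries. A Polg peak on chromosome 7 from 79453362 to 79454212 had 13.96 ± 0.943 against 4.17 ± 0.563 CPM (log2 change 1.74). In COR, a peak in Nfasc, an axonal adhesion gene, on chromosome 1 from 132737580 to 132739365 had 27.9 ± 0.446 CPM in mutants and 0 in both WT libraries, and a peak in Anks1 on chromosome 17 from 27996198 to 27998459 had 1.30 ± 0.343 against 59.1 ± 34.6 CPM (log2 change −5.51). The edgeR test called 0 of 121536 peaks in PVT and 0 of 123573 in COR (smallest adjusted p = 0.556 and 0.535). Unadjusted p under 0.05 was found for 9835 and 11486 peaks, and DESeq2 called 13187 and 37716.

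In CP no peak passed either. The smallest p belonged to a peak far from Lrrc4c on chromosome 2 from 98666230 to 98666561 with 23.7 ± 2.98 CPM in mutants and 850.3 ± 1102 in WT, and peaks near Ranbp9, Bank1, Nuak1 and Nup35 were at 0 in both WT libraries. A Polg peak from 79453538 to 79456230 on chromosome 7 had 83.7 ± 36.9 against 31.3 ± 22.7 CPM. The edgeR test called 0 of 79535 peaks (smallest adjusted p = 0.373), 5323 had an unadjusted p under 0.05 and DESeq2 called 40334. The CP library WT 2 had 80.8% of peaks at 0. Without WT 1, 5436 peaks passed, without WT 2, 80, and without Polg 2, 1.

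In NAC 5 of 105058 H3K27ac peaks passed with edgeR, 1 higher and 4 lower in mutants. The peak that rose spans the lower end of Camk2a and Arsi on chromosome 18 from 60917781 to 60931609 (742.9 ± 65.6 against 199.8 ± 58.2 CPM, log2 change 1.89, SE 0.32, adjusted p = 0.000214). The peaks that fell lie in Cul2, a ubiquitin ligase scaffold gene, on chromosome 18 from 3395149 to 3395399 (0 in both mutant libraries against 82.6 ± 106.8 CPM, adjusted p = 1.81e-12) and in Kcmf1 on chromosome 6 from 72898893 to 72900453 (0.480 ± 0.170 against 60.1 ± 30.4 CPM, adjusted p = 0.0118). The others lie in Commd1 and Zrsr1 on chromosome 11 from 22971553 to 22973100 (2.36 ± 3.34 against 88.6 ± 79.1 CPM, adjusted p = 0.0261) and in Secisbp2 on chromosome 13 from 51651507 to 51652002 (0 in both mutant libraries against 37.9 ± 36.4 CPM, adjusted p = 0.0414; SD, n = 2 each). The median log2 change of all NAC peaks was 1.09, and the WT 2 library had 69.6% of peaks at 0. The count was 0 without WT 1 or WT 2, 13 without Polg 1 and 201 without Polg 2, and the Camk2a call was lost without any 1 library and with DESeq2 (adjusted p = 0.0943, 2057 peaks called).

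Gene-end peaks of several gene groups had lower log2 changes in NAC than the median of all NAC peaks, which was 1.09. Integrated stress response targets had a median of −0.48 over 29 genes (camera adjusted p = 0.0043, and adjusted p = 0.884 with an estimated correlation). Mitochondrial dynamics and mitophagy genes had −0.28, mitochondrial ribosomal proteins −0.38, mitochondrial chaperones and proteases −0.38, glycolysis and lactate genes −0.13 and ER chaperones −0.31. Cytosolic ribosomal proteins, proteasome subunits, circadian clock genes and histone acetylation enzymes had −0.26, −0.57, −0.41 and −0.62. These 10 of 44 lists passed with camera against all peaks, 0 passed with an estimated correlation (adjusted p = 0.884 for each), and no peak in them was called. Most lists, 40 of 44, lay in that direction, and the 10979 gene-end peaks had a median log2 change of −0.07. Against gene-end peaks alone, a background chosen after the data had been seen, none of the 10 lists passed (adjusted p = 0.786 for integrated stress response targets). Innate immune and interferon-stimulated genes passed in that form alone (median log2 change 2.19 over 10 genes, adjusted p = 0.0255, and adjusted p = 0.884 with an estimated correlation). In the other 4 tables, none of the lists (0) passed with camera against either background or with an estimated correlation, and against all peaks 1, 2, 1 and 0 lists had an unadjusted p under 0.05 in ATAC-seq, PVT, COR and CP.

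Genotype differences at gene ends were then compared between the 4 regions over 5029 genes. The interaction of region and genotype passed for 12 genes with edgeR, and each had both libraries of a genotype at 0 in 1 region. Ndrg4, a gene of neuronal differentiation, had 0 and 0 CPM in CP of WT and 427.7 and 210.6 in CP of mutants, while the other regions had 131.4 to 1003 CPM in every library (adjusted p = 0.00853). Pea15a, an astrocyte phosphoprotein gene, and Adgrl3, which codes for latrophilin 3, were at 0 in COR of WT, and Wscd2 was at 0 in COR of mutants. Cstad, Krba1 and Siah3 were at 0 in CP of WT, and Lrrc24, Gse1, C030006K11Rik, Sh2d6 and Lingo2 in CP of mutants. Lrrc24 and C030006K11Rik had the same values in every CP library (255.3 and 207.0 CPM in WT), so their calls rest on the same reads. Unadjusted, 432 genes had a p under 0.05. With the replicate number as a block no gene passed. With a 500 bp window 1 gene passed, and without CP WT 1, CP WT 2, CP Polg 1 or NAC Polg 2 the count was 724, 70, 7 and 2, with 1 gene without any other library.

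Averaged over regions, 10 genes passed, 4 with a higher and 6 with a lower average in mutants. They were Ndrg4, Adgrl3, Pea15a and Krba1 and, on the lower side, Lrrc24, Wscd2, Gse1, Sh2d6, Fam53b and Lingo2. Each again had both libraries of a genotype at 0 in a region (Fam53b in CP of mutants), so no average fold is given, and the direction of the average rests on that region. Ndrg4 had log2 changes of −0.47, −0.89 and −0.16 in PVT, COR and NAC, and Adgrl3 had −0.58 and −0.19 in CP and NAC. Adjusted p lay between 0.0313 and 0.0413 (edgeR), and 547 genes had an unadjusted p under 0.05. Camk2a had log2 changes of −0.89 in PVT and 1.22, 1.73 and 2.24 in COR, CP and NAC, with an average of 1.08 (SE 0.47, adjusted p = 0.412). H3K27ac in PVT had no peak at the lower end of Camk2a, so its value comes from the upper end and the average mixes different places. With a 500 bp window, or with the replicate number as a block, the count of genes was 0. Without CP WT 1, CP WT 2, CP Polg 2, NAC WT 1, CP Polg 1 and COR WT 1 it was 1027, 91, 67, 48, 15 and 1, and it was 0 without any other library.

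Chromatin and RNA differences between genotypes in PVT had correlations near 0 across genes. Gene-end ATAC-seq changes and RNA changes had r = 0.0129 over 11727 genes (Spearman 0.00589, same sign in 50.2%). H3K27ac and RNA changes had r = −0.00400 over 10872 genes (Spearman 0.00519, same sign in 50.8%), and r was 0.00690 over genes with at least 10 CPM and 0.00364 without the H3K27ac library WT 1. ATAC-seq and H3K27ac changes had r = −0.00441 over 10380 genes (Spearman 0.0184, same sign in 51.0%). RNA was from euthymic COX-positive samples and chromatin from sorted neuronal nuclei, and genes are not independent replicates. With edgeR, 0 genes were called for RNA genotype, 0 peaks for H3K27ac in PVT and 1 for ATAC-seq. Correlations near 0 therefore do not show that chromatin and RNA differences disagree.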

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

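Of the tests in this part, the ratio of counts between genes with and without chromatin peaks, the spread of highly counted genes and the DESeq2 calls over other splits were chosen after their results had been seen, as were the libraries left out in the test of region by genotype.

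Polg and Camk2a each had single RNA libraries far from the others of their group. Polg stood at 199.9 CPM in 1 euthymic COX-positive mutant library, against 0.559 to 2.40 CPM in the other 3. Camk2a stood at 54.0 CPM in another euthymic COX-positive library, at 89.6 CPM in a euthymic COX-negative one and at 116.9 CPM in a depressive COX-positive one. The euthymic COX-negative library with 83.3% of its counts in satellite-like loci had 27148 genes with a count. A euthymic COX-positive library had a rank correlation of 0.805 between counts and gene span, lower than in the other 3 of its group. These 6 values came from 30 groups of values examined for a value far apart. The cut-off gives about 1 in 20 groups by chance only for normally distributed values. CPM in this data set were often high in single libraries, so 6 of 30 is not shown to exceed chance.

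Single genes were high in some RNA libraries of a group and near 0 in others, and the median coefficient of variation within groups was 1.13 over the 10814 genes with a mean of at least 500 counts, where 4 libraries can give at most 2. Counting error at such counts is far smaller, and the value was 0.896 for the 1012 most highly counted of them. A candidate explanation is that few starting molecules of each gene entered a library made with the low-input kit, which would give such a spread at high counts. Differences between animals in a group stay open as well and were not tested, since the labels do not say which libraries came from which animal.

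Counts per gene followed gene span, and the 6779 genes without an H3K27ac or ATAC-seq peak at an end in PVT had 0.876 times the counts per kb of the 10134 genes with both (median over 10 span classes, 0.707 to 1.18 over libraries). Ratios over the classes lay between 0.758 and 4.43, the highest in the class of shortest genes. Genes without such peaks were read nearly as often as genes with them, which may point to reads from genomic DNA in these libraries, as a hypothesis. Other values do not go with even reads from genomic DNA. From span class 2 to class 10, median CPM per kb rose from 0.0954 to 0.418 without peaks and from 0.105 to 0.462 with both (0.359 and 0.0811 in class 1). Olfactory receptor genes, not matched for span, had a median above that of synaptic genes in 2 of 20 libraries. The cause was not tested. Deviations of neighbouring genes 1 to 20 kb apart correlated at r = 0.0999 over 9450 pairs, against 0.0197 for genes on different chromosomes, so amplified genomic fragments shared by neighbours cannot be told apart from domains of shared activity, which such a small value does not separate. RNA from unspliced nuclear transcripts stays open and was not tested.

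Behavioural state averaged over COX classes gave 354 genes, and chance could not be excluded, since 49 of 100 splits gave as many and the highest other split gave 2121. The count was 0 without any 1 of the 16 mutant libraries. For COX class averaged over states and for the interaction the real count was 0, which every split reaches (100 of 100), so the splits say nothing about these comparisons, and other splits gave up to 1492 and 1612 genes. Splits with several times the real count point to a structure of the RNA libraries that the groups do not follow, although counts can also jump where many adjusted p lie near the threshold, as the smallest ones of 0.0538 and 0.0534 in these comparisons did. In the 5 pairwise RNA contrasts the real count was 0, as was the highest other count, so that all 35 splits of each reach it and say nothing about them. DESeq2, run on the 28446 genes tested with edgeR and all 20 libraries, called 1495 genes for genotype, while 18 of 21 splits of the WT and euthymic COX-positive mutant libraries gave as many and the highest other gave 2201, so chance could not be excluded there either.

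The genotype difference at H3K27ac gene ends differed between regions for 12 genes, among them Ndrg4, Pea15a and Adgrl3, by the test of that difference itself. Chance could not be excluded: 17 of 100 splits gave as many, with 19 in the highest other split. Averaged over regions, 10 genes passed, 24 of 100 splits gave as many and the highest other gave 22. With the replicate number as a block no gene passed in either test. Without CP WT 1, CP WT 2, CP Polg 1 and NAC Polg 2 the count of 12 became 724, 70, 7 and 2, and 1 without any other library. The count of 10 became 1027, 91, 67, 48, 15 and 1 without CP WT 1, CP WT 2, CP Polg 2, NAC WT 1, CP Polg 1 and COR WT 1, and 0 without any other.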

How the results depend on the processing

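Of the alternatives in this part, those chosen after the data had been seen were the RNA fit without satellite-like loci, all those for regions against other regions, for genotype averaged over regions and for the Polg and Camk2a loci, the gene-end background of the list tests, and the left-out libraries for region by genotype and for correlations.

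Over all alternatives, 317 values of the comparisons stayed close to the reported one, 166 moved further and 4 reversed. Close meant within 1.5 times a reported count, with a count of 0 that stayed at 0 included, or within the spread of a correlation. For the Polg and Camk2a loci it meant the same direction and side of the threshold in the exact test. Of the values for named chromatin peaks and gene ends, 380 kept direction and side of the threshold, 153 lost the call, 36 gained it and 4 reversed. For named RNA genes these were 677, 624, 67 and 1. In the simulation of RNA genotype, a 16-fold change was recovered for 0 of 100 genes, and for 100 with a coefficient of variation of 0.2. The simulated counts did not behave like the real ones, so these values do not show what limited the real contrasts. The libraries CP WT 2 and NAC WT 2 had the lowest total counts of their tables, with 80.8% and 69.6% of peaks at 0. Where an alternative moved a value, the cause was not tested.

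DESeq2 in place of edgeR called 1125 genes for RNA genotype (0 with edgeR), 2103 and 2019 for COX class in euthymic and depressive mice (0 and 0) and 1733 and 2537 for state in COX-positive and COX-negative libraries (0 and 0). It called 2192 for COX averaged (0), 2110 for state averaged (354) and 1976 for the interaction (0). In chromatin it called 3 peaks in ATAC-seq (1), 13187 in PVT (0), 37716 in COR (0), 40334 in CP (0) and 2057 in NAC (5). With voom, 1 and 1 genes passed for state in COX-positive and COX-negative libraries and 0 for state averaged. Without a filter on low counts, edgeR called 2, 458 and 586 genes for genotype and for COX in euthymic and depressive mice, 1170 for state in COX-negative libraries and 1628, 1887 and 1582 for COX averaged, state averaged and the interaction, with 1 peak in CP and 29 in NAC. For COX averaged, state averaged and the interaction, DESeq2 size factors gave 377, 780 and 378 genes, a stricter filter 283, 206 and 188, and the fit without satellite-like loci 317, 670 and 280. State averaged gave 0 with only the groups of the contrast, 0 with detected genes as a covariate and 0 to 0 without each of the 16 mutant libraries. Of its 354 genes, 354, 353, 165, 156 and 342 were shared with DESeq2 size factors, no filter, the stricter filter, DESeq2 and the fit without satellite-like loci.

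In NAC, DESeq2 size factors gave 11 peaks and total counts 80, and total counts gave 7 peaks in CP. Leaving out libraries gave 0 (WT 1) to 4 (Polg 1) peaks in ATAC-seq, 0 to 5436 in CP (5436, 80 and 1 without WT 1, WT 2 and Polg 2) and 0 to 201 in NAC (0, 0, 13 and 201 without WT 1, WT 2, Polg 1 and Polg 2). The adjusted p of the NAC peak at Camk2a was 0.335 to 1 without single libraries and 0.0943 with DESeq2. The 10 gene lists of NAC became 0 with an estimated correlation and 1, another list, against gene-end peaks alone.

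Region by genotype gave 1 gene with a 500 bp window (12 reported) and 1 to 724 without single libraries (724, 70, 7 and 2 without CP WT 1, CP WT 2, CP Polg 1 and NAC Polg 2, 1 otherwise). Averaged over regions the window gave 0 (10 reported) and left-out libraries 0 to 1027 (1027, 91, 67, 48, 15 and 1 without CP WT 1, CP WT 2, CP Polg 2, NAC WT 1, CP Polg 1 and COR WT 1, 0 otherwise). For PVT, COR, CP and NAC against the other regions, gene ends without a listed peak taken as 0 gave 7305, 5830, 4352 and 5111 genes, counts per kb of peak 0, 0, 29 and 0, and total counts 99 in CP. Leaving out libraries gave 92 to 398, 12 to 150, 34 to 279 and 0 to 103, with each library under the other observations.

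The ATAC-seq peak at the upper end of Polg, from 79466096 to 79466520 on chromosome 7, had a log2 change of −0.00501, which reversed to 0.0152 with DESeq2 size factors, 0.0224 with a stricter filter and 0.00840 with DESeq2, and ran from −0.128 (without Polg 1) to 0.130 (without Polg 2). Polg RNA between genotypes had a log2 change of −1.06 to 5.18 without single libraries, and the −1.06 came without the mutant library with 199.9 CPM. Over the rest of Camk2a the difference of −0.05 reversed to 0.00334, 0.0230, 0.0360 and 0.131 without PVT Polg 2, COR WT 1, COR Polg 1 and CP WT 1, with a lowest value of −0.229 without CP WT 2, and was −0.22 with total counts. Over the whole span of Polg the difference of 1.76 was 1.33 with a pseudocount of 5 CPM, 1.64 with total counts, 1.57 to 1.95 without single libraries and 1.11 without the NAC table. The difference over the rest of Polg was 1.77 with a pseudocount of 5 CPM and 2.33 with total counts, and at the lower end of Camk2a 1.79 and 1.68.

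The correlation of COX differences between states (0.00895) was −0.0360 over genes of at least 10 CPM and −0.00631 to 0.0206 without single libraries, and that of state differences between COX classes (0.00948) was 0.0168 and −0.00277 to 0.0238. ATAC-seq with RNA (0.0129) had 0.00793 and 0.00564 to 0.0165, and H3K27ac with RNA (−0.00400) had 0.00690 and −0.0142 to 0.00364.

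No paired analysis was possible because the RNA columns carry no replicate numbers, so the planned replicate block for the RNA contrasts and their gene lists was not run. Chromatin libraries of equal number share only a number: their deviations correlated at r = −0.0514 (ATAC-seq), −0.0124 (PVT), 0.0168 (COR), −0.0267 (CP) and −0.0443 (NAC). With the number as a block, 2, 0, 10, 1 and 2 peaks passed in these tables, 0 genes for region by genotype and 0 averaged over regions. The NAC peak at Camk2a had an adjusted p of 0.560 in that fit.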

Other observations

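Of the tests in this part, the comparison of each region with the other regions, its version per kb of peak and the tests of the Polg and Camk2a loci were chosen after the data had been seen.

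Markers of the habenula, which borders the PVT, had H3K27ac peaks at gene ends in PVT libraries. Of 17 such genes 12 had a peak in PVT, against 7 in COR, 8 in CP and 10 in NAC. The share in PVT, 70.6% against 55.1% of other genes, did not pass (Fisher's exact test, adjusted p = 0.526). Gpr151, an orphan receptor gene of habenula neurons, had 997.9 ± 248.3 CPM in PVT, 54.4 ± 30.4 in COR and 77.5 ± 52.4 in NAC and no peak in CP. Nhlh2, a transcription factor gene, had 339.1 ± 59.4 CPM in PVT alone, while Pou4f1, Chrnb4 and Tac2 had no gene-end peak in any region. Chrnb3 had 5.27 ± 5.91 CPM in PVT and 410.6 ± 241.8 in COR, Gng8 had 8.42 ± 9.93 in PVT and 37.6 ± 27.3 in NAC, and Tac1 and Calb1 had peaks in other regions and none in PVT (SD, n = 4 per region, both genotypes together). Glial genes carried peaks in NeuN-sorted nuclei too: S100b had 186.0 ± 34.9 CPM in PVT, Sparcl1 563.4 ± 228.3 in COR, and Apod, a lipocalin gene, 756.8 ± 238.7 in NAC against 12.02 ± 13.96 in PVT.

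Gene ends of 4 genes were higher in the caudate putamen than the mean of the other regions, both by summed counts and per kb of peak. Ppm1f, a protein phosphatase gene, had 1016 ± 240.3 CPM in CP and 535.5 ± 399.9 in the other regions, and Pde1b, a phosphodiesterase gene of striatal neurons, had 1581 ± 975.8 against 647.8 ± 570.2. C1qtnf4 had 1450 ± 325.9 against 683.6 ± 601.7 CPM and Nckap1l, a gene of blood cells, 1434 ± 870.1 against 564.9 ± 488.7 (SD, n = 4 and 12). Per kb of peak the log2 changes were 1.68, 2.08, 1.46 and 1.91, with adjusted p of 0.0213, 0.0213, 0.0418 and 0.0435 (edgeR). Their libraries overlapped those of the other regions. Pde1b and Nckap1l had similar values, with 321.9 and 290.1 CPM in the lowest CP library and 1982 and 1704 in the highest other library. A peak near the ends of several genes counted for each of them, so these 2 genes may not be separate results. C1qtnf4 had 1411 ± 118.5 CPM in NAC and 52.4 ± 20.6 in PVT, Ppm1f had 67.108 ± 14.002 in PVT, and Nckap1l had 134.9 ± 75.7 in COR.

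By summed counts edgeR called 189 genes for PVT against the other regions, 34 for COR, 62 for CP and 22 for NAC. Other splits gave at most 114, 1, 1 and 39 genes, and 1, 1, 1 and 2 of 100 splits gave as many, the real one included. Peaks were drawn separately in each region, so only the real grouping keeps that built-in difference, and the splits cannot say whether chance is excluded. Changes in summed counts followed the length called as peak, with rank correlations across genes of 0.831, 0.762, 0.762 and 0.705. Dcstamp, for example, had 11410 ± 1795 CPM over 96.0 kb of peak in PVT and 412.0 ± 197.1 CPM over 5.33 kb elsewhere. Per kb of peak, 0, 0, 29 and 0 genes passed, with 159, 50, 634 and 52 at an unadjusted p under 0.05, so the calls for PVT, COR and NAC may rest on how much was called as peak around a gene. All 29 per kb calls in CP were higher there, and CP had the shortest length called as peak per gene, with a median of 0.983 kb against 1.80 to 2.36 kb in the other regions, so these calls may rest on peak length as well. The count of 189 became 96, 97, 92 and 98 without PVT WT 1, WT 2, Polg 1 and Polg 2 and 333 and 398 without CP WT 1 and WT 2. The count of 34 became 12 and 12 without COR Polg 1 and Polg 2 and 150, 149 and 104 without CP WT 1, WT 2 and Polg 2. For CP the count of 62 became 34, 41, 39 and 37 without PVT WT 1, WT 2, Polg 1 and Polg 2, 41 without COR WT 2, 279, 238, 36 and 192 without CP WT 1, WT 2, Polg 1 and Polg 2, and 39, 35 and 35 without NAC WT 1, Polg 1 and Polg 2. For NAC the count of 22 became 6, 4, 8 and 12 without PVT WT 1, WT 2, Polg 1 and Polg 2, 12 and 4 without COR Polg 1 and Polg 2, 103, 92 and 65 without CP WT 1, WT 2 and Polg 2, and 4, 0, 8 and 4 without NAC WT 1, WT 2, Polg 1 and Polg 2.

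Polg and Camk2a read higher in mutant chromatin over parts chosen after their values had been seen, and it was asked whether reads from a transgene could account for it, since the Polg(D181A) line, as background that is not stated in the labels, carries one that joins a Camk2a promoter to Polg coding sequence. The log2 change over the rest of the Polg span exceeded that of its upper end by 2.98 (SD 1.79 over 3 tables, 1.31 to 4.87), a mean that leans on COR, while in H3K27ac of PVT the upper end was itself higher in both mutant libraries (4.97 ± 3.08 against 2.62 ± 0.209 CPM, SD, n = 2 each). The change at the lower end of Camk2a exceeded that over the rest of Camk2a by 1.83 (SD 0.66 over 4 tables, 1.32 to 2.78). Both parts were chosen for this pattern, so reads from such a transgene, higher activity of the mouse's own Polg gene and a change in the regulation of Camk2a itself cannot be told apart. Ranked by the rise in mutants over the whole span, with falls not counted, Polg was 22 of 9132 genes. For 73 genes both mutant libraries exceeded both WT libraries in at least 4 of 5 tables, against 30.5 by chance. That chance value takes the tables as independent, and it would not hold if tables share animals.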
